A study of Macaca fascicularis with 16 samples.

How the data were processed

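RNA sequencing counts of 16 libraries of aorta from normal young cynomolgus monkeys (Macaca fascicularis) were analysed, 4 from each of the ascending, descending, suprarenal and infrarenal regions. According to the labels, total RNA was extracted with a kit for fibrous tissue and libraries were made with a NEBNext Ultra RNA kit. The authors named fastp, HISAT2 (2.0.5) and featureCounts (1.5.0-p3), and the deposited values are raw counts per NCBI GeneID. The genome build and annotation are not given in the sources used here. The deposited series table was checked against the library files and held the same values.

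The files held 32846 rows, of which 32822 were GeneIDs and 24 were names of mitochondrial RNAs. Symbols came from the annotation of the telomere-to-telomere assembly MFA8v1.1, used for names only, and 24609 rows (74.9%, holding 97.2% of the counts) matched it. Library totals, in units of 1e6 counts, ran from 14.4 to 21.41. Genes were kept with filterByExpr of edgeR at a minimum count of 10 and a minimum total of 15, which left 15926 genes (14661 with a symbol) and 99.9% of the counts.

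Counts were normalized with TMM factors and fitted with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with a mean for each region and all 16 libraries in the model. The common dispersion was 0.146, a biological coefficient of variation of 0.382, with 12 residual and 3.46 prior degrees of freedom. The lowest chi-square per degree of freedom between libraries of the same region was 27.5, so no library repeated another. Tests were made of any difference among the 4 regions, of the infrarenal region against the mean of the other 3, of the 6 pairs of regions, and of genes with the same sign in all 3 infrarenal pairs. Benjamini-Hochberg adjusted p-values under 0.05 were called. For NOTCH3, ELN and FBN1 an exact permutation test was added, with 1820 splits for the infrarenal region against the rest and 70 for each pair.

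Gene lists were written before the data were examined, from general knowledge of the tissue. They covered elastic fibre, fibrillar collagen, basement membrane, proteoglycan, contractile smooth muscle, Notch pathway, anterior HOX, posterior HOX, heart field and neural crest factors, TGF-beta and BMP, WNT pathway, renin-angiotensin, extracellular proteolysis, heritable thoracic aortic disease, ion channels of muscle, oxidative phosphorylation, cholesterol synthesis, immediate-early and stress, and markers of endothelial, fibroblast, white adipocyte, brown adipocyte, cardiac muscle, skeletal muscle, macrophage, lymphocyte, mast, Schwann, mesothelial and pericyte and mural cells. These 30 were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and a prior count of 2. Of 32 lists, red blood cell markers had 0 tested genes and adrenal and chromaffin markers 1, so they were not run. Members were also adjusted over the list alone. A list's score in a library is the mean of its members' log2 CPM, each centred on its mean over the 16 libraries.

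Genes were named by a rule. NOTCH3, ELN and FBN1 were given in every contrast. For the infrarenal region against the rest, the 10 largest changes in each direction were taken among called genes with a symbol, a mean log2 CPM of at least 1 and infrarenal libraries all beyond the other 12. For each pair the 5 largest in each direction without overlap were taken under the same limits, so scarcer or unnamed genes with larger changes were passed over, for each list up to 4 members with the smallest p, and for the test of any difference the 5 smallest p. Other genes, such as UCP1, NLRP7, HES1 and MYL9, were chosen after the values were seen. Where a region held 3 counts or fewer, the ratio of summed counts is given with an exact 95% interval, or as a bound against a floor of 3 counts. Such intervals and floors cover counting error only.

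The alternatives were a block for the replicate number, RLE size factors, library totals alone, no filter beyond 1 count, a filter of CPM of at least 1 in at least 4 libraries, DESeq2 1.42.0, limma voom, an added minimum log2 change of 1, only the libraries compared, and each of the 16 libraries left out in turn. Lists were also tested with an estimated correlation and with fry. A fit without infrarenal replicate 1, ascending replicate 4 and suprarenal replicate 3 was added after the data were seen, as were the fits without 1 library for the lists in pairs of regions.

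The pipeline was tested on simulated data. With changes put into counts like these, the infrarenal comparison found 48.5% of 97 genes changed 2-fold and 74.5% of 98 changed 4-fold, with 9 false among 129 calls. The 3 infrarenal pairs found 21.6% to 28.9% of the 2-fold and 65.3% to 66.3% of the 4-fold genes, so a gene without a call is not shown to be unchanged. A list of 20 genes changed 1.5-fold had an adjusted p of 7.83e-14, and 0 of 30 unchanged lists were called. Genes were drawn independently there and no library stood apart. The simulation therefore cannot show that the preset correlation suits lists whose genes move together. Coordinates were not used here, and transcripts and splicing were not analysed here. A few single-gene results are not reported here.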

Results

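Gene expression was measured by RNA sequencing in 16 libraries of aorta from normal young cynomolgus monkeys (Macaca fascicularis). The libraries came from 4 regions of the vessel, namely the ascending, descending, suprarenal and infrarenal aorta, with 4 libraries in each. The total count per library, in units of 1e6 counts, ran from 15.55 to 16.51 in the ascending region, from 15.95 to 17.75 in the descending region, from 14.65 to 21.41 in the suprarenal region and from 14.4 to 17.63 in the infrarenal region. Library numbers run from 1 to 4 in every region, and the labels do not say that the libraries are separate animals, so the p-values measure the spread between these libraries only. In deviations from the region means, 15 of 16 libraries lay closest on average to libraries of their own number in other regions. The main tests do not model the number. Infrarenal replicate 1 stood apart from the rest. Its TMM factor was 0.736 against 0.977 to 1.08 in the others, its 10 largest genes held 12.6% of its counts, and it lay at -149 on the first principal component, which held 25.6% of the variance. The 76 ribosomal protein genes lay 1.60 log2 units above the mean of the other infrarenal libraries in it, and 22 genes of very long transcripts lay at -1.35. Adipocyte, endothelial, lymphocyte and mesothelial markers also differed widely between libraries of the same region.

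**Figure D1:**
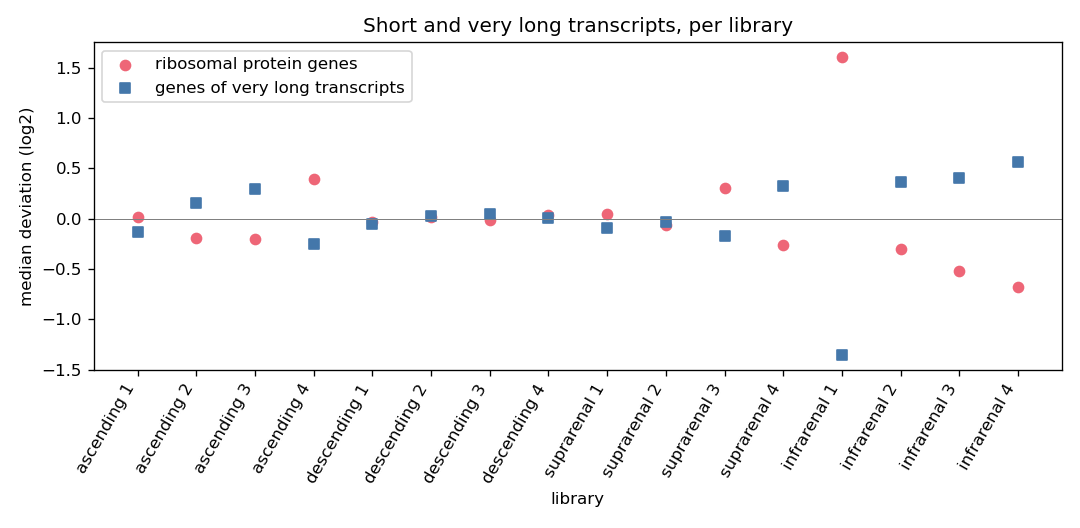
Median deviation (log2) of ribosomal protein genes (circles) and of genes of very long transcripts (squares) in each of the 16 libraries, from the mean of the other libraries of its region. Infrarenal 1 has the widest gap, 2.96. The gap in the other infrarenal libraries, whose reference mean includes infrarenal 1, runs from -1.23 to -0.67. In the other regions the gap runs from -0.59 to 0.65.

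The first comparison set the infrarenal aorta against the mean of the other 3 regions and asked which genes set that segment apart, NOTCH3 and the elastic fibre genes first. NOTCH3 (GeneID 102120202), a Notch receptor of vascular smooth muscle and pericytes, rose by 1.93 on the log2 scale (SE 0.19, adjusted p = 8.44e-05). Its level was 458 ± 49.6 CPM (SD, n = 4) in the infrarenal region, 216 ± 41.7 in the suprarenal, 142 ± 64.2 in the descending and 56.3 ± 12.2 in the ascending region. The lowest of the 4 infrarenal libraries, at 402 CPM, lay above the highest of the 12 others, at 256 CPM. An exact two-sided permutation test of that difference gave p = 0.0011 over 1820 splits, of which the smallest possible is 0.000549, and an adjusted p of 0.0132 over 12 such tests of NOTCH3, ELN and FBN1. ELN (GeneID 102118050), which encodes tropoelastin, did not pass the edgeR test (log2 difference -1.02, SE 0.47, adjusted p = 0.35). It averaged 159 ± 96.1 CPM in the infrarenal region and 261 ± 102, 405 ± 177 and 317 ± 180 in the suprarenal, descending and ascending regions. FBN1 (GeneID 102127300), the main protein of microfibrils, did not pass either (-0.56, SE 0.19, adjusted p = 0.154), with 378 ± 88.3 CPM in the infrarenal region and 563 ± 128, 673 ± 99.4 and 460 ± 106 in the same order. Both had an adjusted p of 0.0518 in the exact permutation test.

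**Figure D2:**
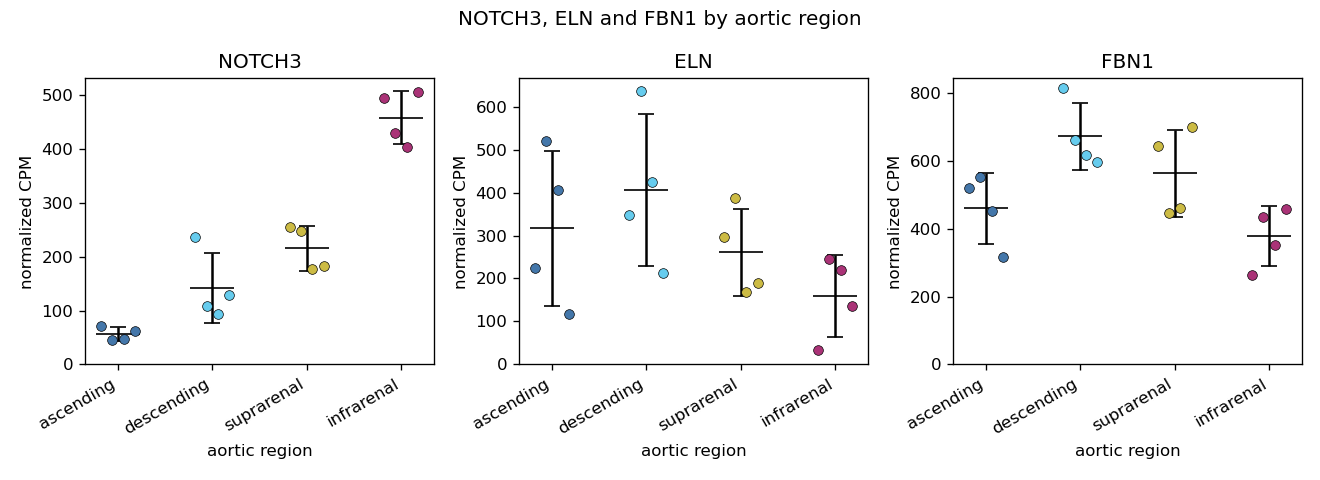
Normalized CPM of NOTCH3, ELN and FBN1 in each library (points, 4 per region), with the mean and SD of each region (bars). The infrarenal libraries hold the 4 highest NOTCH3 values, from 402 to 505 CPM, while infrarenal ELN overlaps every region and FBN1 all but the descending.

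In all, 474 of 15926 tested genes passed an adjusted p of 0.05 in this comparison, 218 higher and 256 lower in the infrarenal aorta, and 2185 had an unadjusted p under 0.05 where chance alone gives 796. With library totals in place of TMM factors the count was 464, with 159 higher and 305 lower. Among genes with a mean log2 CPM of at least 1 whose infrarenal libraries all lay above every other library were positional transcription factors of the HOX family, HOXA10 (5.15), HOXA9 (4.64) and HOXD9 (4.25). HOXA10 averaged 37.4 ± 8.47 CPM in the infrarenal region against 6.22 ± 4.94, 1.86 ± 0.636 and 0.0922 ± 0.0620 in the suprarenal, descending and ascending regions. P2RX1, an ATP-gated cation channel of smooth muscle, rose by 4.66 to 190 ± 58.1 CPM. The potassium channel genes KCNAB1 (3.93) and KCNT2 (3.82), the BMP antagonist GREM1 (3.69), the angiopoietin ANGPT2 (3.46), CTNNA3 (4.23), a catenin of cell junctions, and NKAIN2 (4.70) also rose. Among genes that fell, RBFOX1, a regulator of splicing, changed by -7.79 (SE 0.93) and averaged 0.0916 ± 0.106 CPM in the infrarenal region against 8.27 ± 7.35, 29.6 ± 13 and 48.9 ± 23.4 in the suprarenal, descending and ascending regions. CTNND2, a catenin, changed by -5.95, the WNT signalling enhancer RSPO2 by -4.66, the pentraxin NPTX2 by -4.65, and SOX9, a transcription factor of cartilage and neural crest, by -3.87. C8H8orf34 (-4.65), CRMP1 (-3.91), SUSD4 (-3.90), IGFN1 (-3.87) and TMEM151B (-3.68) fell as well, and the adjusted p-values of these 20 genes ran from 2.07e-06 for HOXA10 to 0.00727 for NPTX2. Without infrarenal replicate 2 the number of genes that passed was 267, while DESeq2 called 852, and leaving out infrarenal replicate 1, ascending replicate 4 and suprarenal replicate 3 together gave 1607, with 874 higher and 733 lower. The fits without infrarenal replicates 2, 3 and 4 also had more genes higher than lower (135 and 132, 194 and 186, 188 and 175). The calls of RBFOX1, CTNND2, RSPO2 and IGFN1 were each lost in 1 of the 24 other settings, with adjusted p-values up to 0.0561, 0.290, 0.0702 and 0.0732.

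Of the gene lists fixed before the data were examined, 8 of 30 passed camera in this comparison. The posterior HOX list (paralog groups 6 and above) moved most. All 15 tested members were higher, 13 rose over all genes and 15 when adjusted over the list alone, with a median of 3.14 and of 2.60 with HOXB8 and HOXD10 at their bounds (adjusted p = 2.02e-29, and adjusted p = 0.0083 with an estimated correlation). Of the elastic fibre list, 18 of 21 tested genes were lower and 3 higher, with a median of -0.28 (adjusted p = 6.12e-05, and adjusted p = 0.0379 with an estimated correlation). EMILIN2, a glycoprotein that binds elastic fibres, fell by 1.01 (SE 0.17), the fibrillin FBN2 by 1.30 and the microfibril protein MFAP2 by 0.97, while FBLN5, which is needed for elastic fibre assembly, had a value of -0.66 (adjusted p = 0.105). No member rose, 18 did not pass over all genes, and 7 fell when adjusted over the list alone. The mean score of the list was -0.36 ± 0.05 (SD, n = 4) in the infrarenal region, 0.01 ± 0.12 in the suprarenal, 0.20 ± 0.13 in the descending and 0.15 ± 0.22 in the ascending region. Of the pericyte and mural cell list, 9 of 11 members were higher (median 0.62, adjusted p = 2.84e-05, and adjusted p = 0.0083 with an estimated correlation). NOTCH3, the adhesion molecule MCAM (1.12), the growth factor receptor PDGFRB (0.69) and the potassium channel KCNJ8 (0.88) rose, and 5 members rose when adjusted over the list alone. Of the 12 genes on that list 5 are also on another list, and smooth muscle of the aortic wall expresses several of them. FBN2 and MFAP2 each lost their call in 13 of 16 fits that left out 1 library (adjusted p up to 0.126 and 0.164), and KCNJ8 lost its call in 4. Without infrarenal replicate 1 the value of KCNJ8 was 0.41 (adjusted p = 0.0892).

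**Figure D3:**
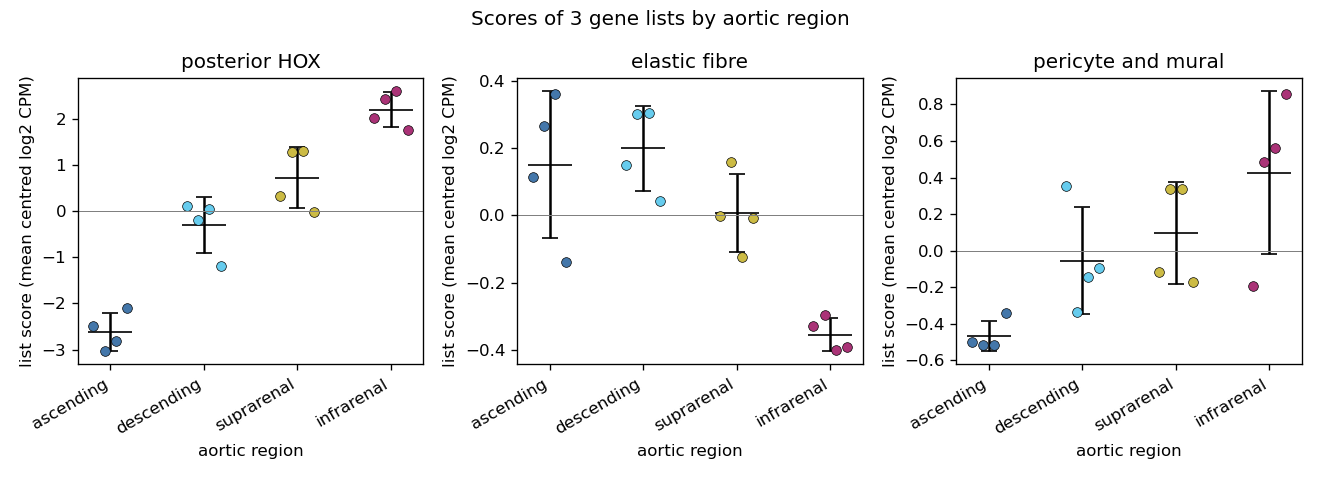
Score of 3 gene lists (mean over members of log2 CPM, centred on each gene's mean over the 16 libraries) in each library (points), with the mean and SD of each region (bars, n = 4). Posterior HOX scores average -2.61 in the ascending and 2.20 in the infrarenal region, and the 4 infrarenal libraries have the lowest elastic fibre scores.

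The other 5 lists passed only with the preset correlation. Oxidative phosphorylation was higher, with 35 of 39 genes up, 0 called and 0 called when adjusted over the list alone (median 0.31, adjusted p = 0.0037, adjusted p = 0.650 with an estimated correlation). Contractile smooth muscle genes were higher in 19 of 28 (median 0.23, adjusted p = 0.024, adjusted p = 0.650 with an estimated correlation), with MCAM called and 6 called when adjusted over the list alone. Both medians turned negative without infrarenal replicate 1, at -0.09 and -0.03, and MYL9, a myosin light chain, had 16050 ± 14990 CPM in the infrarenal region because of that library. Schwann cell markers were lower in 12 of 17 (median -0.66, adjusted p = 0.00966, adjusted p = 0.650 with an estimated correlation). The call of the Schwann cell list was lost without suprarenal replicate 3, infrarenal replicate 1 or infrarenal replicate 2 (adjusted p up to 0.111). Endothelial markers were higher in 22 of 24 (median 0.52, adjusted p = 0.0458, adjusted p = 0.762 with an estimated correlation). ESAM, an endothelial adhesion molecule, rose by 1.72, the 1 gene called on either adjustment, and the list's median was -0.04 without infrarenal replicate 3. The endothelial call was lost in most of the 16 fits without 1 library (adjusted p up to 0.707). The list of genes of heritable thoracic aortic disease was lower in 18 of 25 (median -0.15, adjusted p = 0.0458, adjusted p = 0.650 with an estimated correlation), with FBN2 as its single call on either adjustment and 21 of its 26 genes shared with other lists. Its call was lost in 8 of 16 fits without 1 library (adjusted p up to 0.202).

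Single members also changed in lists that did not pass. Of 31 Notch pathway genes (adjusted p = 0.123), NOTCH3, its ligand JAG1 (1.35, SE 0.16, adjusted p = 0.000257) and the HES-family repressor HES4 (2.37, adjusted p = 0.00129) rose, 3 on either adjustment, while HES1 had a value of 0.94 (adjusted p = 0.243). JAG1 averaged 296 ± 31.1 CPM in the infrarenal region and 151 ± 28.4, 117 ± 38.5 and 89.1 ± 13 in the suprarenal, descending and ascending regions. Of the 13 anterior HOX genes (adjusted p = 0.274), 4 rose, among them HOXC4 (2.47), HOXD4 (2.23) and HOXB5 (1.57), and HOXA4 fell by 2.19, with 5 and 2 when adjusted over the list alone. Of 29 heart field and neural crest factors (adjusted p = 0.0723), SOX9, TBX20 (-3.45), HAND2 (-1.18) and 1 more fell and TBX2 (1.57) rose, with 6 and 2 when adjusted over the list alone. Of 27 ion channels of muscle (adjusted p = 0.213), KCNA5 (1.91), CACNA1H (2.39), KCNJ8 and 1 more rose, and 5 rose when adjusted over the list alone. Collagen COL1A1 rose by 1.07 within the fibrillar collagens (adjusted p = 0.155, 3 of 20 when adjusted over the list alone), a call lost without infrarenal replicate 2 or 4 (adjusted p up to 0.106). In the TGF-beta and BMP list (adjusted p = 0.471) GREM1 and THBS1 (1.33) rose and BMPR1B (-2.09) fell, with 6 and 2 when adjusted over the list alone. RSPO2 fell and LRP5 (0.64) rose in the WNT list (adjusted p = 0.828, 2 and 2 when adjusted over the list alone). Among proteoglycans (adjusted p = 0.411) SULF2 (-1.67) fell and ACAN (3.29) rose, 1 each when adjusted over the list alone. The ACAN call was lost without infrarenal replicate 1 (adjusted p = 0.105). PLAT (-1.05) fell in the extracellular proteolysis list (adjusted p = 0.349, 3 when adjusted over the list alone). The cholesterol synthesis list had an adjusted p of 0.700. KRT8 (-2.67) fell among mesothelial markers (adjusted p = 0.258, 1) and CASQ1 (-2.03) and ACTN3 (-1.15) among skeletal muscle genes (adjusted p = 0.471, 2 and 1 up). FABP3 (2.36) rose in the brown adipocyte list (adjusted p = 0.700, 1). BMPR1B, THBS1, HOXB5, LRP5, PLAT, CASQ1 and ACTN3 each lost their call in 1 to 12 of the 16 fits that left out 1 library.

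No member passed over all genes in the other lists. Their adjusted p-values were 0.0544 for macrophage, 0.113 for cardiac muscle, 0.213 for mast cell, 0.276 for immediate-early and stress, 0.450 for renin-angiotensin, 0.518 for white adipocyte, 0.705 for lymphocyte, 0.828 for basement membrane and 0.922 for fibroblast genes. Adjusted over the list alone, 2 cardiac muscle genes and 1 immediate-early gene fell, 1 basement membrane gene rose and 0 passed in the remaining 6. Test and median differed in sign for the WNT, lymphocyte, extracellular proteolysis and cholesterol synthesis lists (medians 0.03, -0.03, 0.04 and 0.10), and the brown adipocyte list had a mean of -0.01 beside a median of 0.46. White adipocyte scores varied widely within regions, at 0.11 ± 1.83 in the infrarenal, 0.32 ± 1.78 in the suprarenal, 1.21 ± 1.45 in the descending and -1.63 ± 1.02 in the ascending region (SD, n = 4).

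Against the adjacent suprarenal aorta, 32 genes differed, 3 higher and 29 lower in the infrarenal region. An unadjusted p under 0.05 was found for 918, where chance alone gives 796. HOXA10 rose by 2.58 (SE 0.44, adjusted p = 0.0293) and PTP4A1, a protein tyrosine phosphatase, by 0.94 (adjusted p = 0.0423), from 52.3 ± 12.5 to 100 ± 16 CPM (SD, n = 4). PCP4, a calmodulin-binding protein, had 362 counts over the 4 infrarenal libraries and 3 over the 4 suprarenal libraries, a ratio of 135 (95% counting interval 45.7 to 656). RBFOX1 fell by 6.32 (adjusted p = 0.0143), NPTX2 by 4.88, C8H8orf34 by 3.92, SHISA9 by 3.91 and TMEM151B by 3.40 (adjusted p = 0.0143). With 1 library left out, PTP4A1 lost its call in 13 of 16 fits (adjusted p up to 0.143), NPTX2 and SHISA9 in 12 each (0.187 and 0.192), and HOXA10 and C8H8orf34 in 5 each (0.128 and 0.143). RBFOX1 lost it without infrarenal replicate 2 or 4 (up to 0.0932) and TMEM151B without infrarenal replicate 2 (0.0624). For NOTCH3, infrarenal versus suprarenal, the difference was 1.09 (SE 0.26, adjusted p = 0.131), which did not pass the edgeR test over all genes. The 4 infrarenal libraries lay above the 4 suprarenal ones, and the exact permutation p of 0.0286 is the smallest that 70 splits allow. It passed in 3 of 25 other settings, among them DESeq2 (adjusted p = 0.00669) and the edgeR fit without descending replicate 1 (adjusted p = 0.0378), and the adjusted p reached 0.424 at most. ELN (-0.71, adjusted p = 0.947) and FBN1 (-0.58, adjusted p = 0.733) did not pass. Camera passed 8 lists here and none of them with an estimated correlation. Posterior HOX genes were higher in 15 of 15 (median 0.83, adjusted p = 7.48e-13, adjusted p = 0.0716 with an estimated correlation), with HOXA10 called and 4 when adjusted over the list alone. Elastic fibre genes were lower in 19 of 21 (median -0.33, adjusted p = 0.000392, adjusted p = 0.0716 with an estimated correlation), with 0 called and 2 when adjusted over the list alone. Pericyte markers (0.29, adjusted p = 0.000392, adjusted p = 0.0574 with an estimated correlation, 0 called and 4 when adjusted over the list alone), contractile genes (0.27, adjusted p = 0.000622) and oxidative phosphorylation (0.36, adjusted p = 2.38e-07) had positive medians. Macrophage (-0.58, adjusted p = 0.000488), mast cell (-1.13, adjusted p = 0.00756) and Schwann cell (-0.61, adjusted p = 0.00439) markers had negative ones. In these 5 lists 0 genes were called, and 1 Schwann cell gene fell when adjusted over the list alone. The adjusted p with an estimated correlation was 0.136 for mast cell and 0.757 for the contractile, oxidative phosphorylation, macrophage and Schwann cell lists. Without infrarenal replicate 1 the medians of the contractile and oxidative phosphorylation lists were -0.013 and -0.004, and without suprarenal replicate 3 the contractile, macrophage, mast cell and Schwann cell calls were lost (adjusted p from 0.197 to 0.761). The number of genes that passed ran from 3 without infrarenal replicate 2 to 52 without suprarenal replicate 2, was 0 in a fit of these 8 libraries alone, and DESeq2 called 167. With limma voom 15 passed, 9 higher and 6 lower.

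Against the descending thoracic aorta, 263 genes differed, 101 higher and 162 lower in the infrarenal region (2197 at an unadjusted p under 0.05). NOTCH3 rose by 1.69 (SE 0.26, adjusted p = 0.00354), and its ligand JAG1 (1.33) and the repressor HES4 (2.70) rose as well. P2RX1 (5.39), HOXD9 (5.02), DPYSL5 (4.81), CTNNA3 (4.70) and the cartilage proteoglycan ACAN (4.70) rose, without overlap between the libraries of both regions. RBFOX1 (-8.17), CTNND2 (-6.64), RSPO2 (-5.40), the membrane glycoprotein PROM1 (-5.37) and C8H8orf34 (-5.14) fell, and PROM1 averaged 3.45 ± 4.13 CPM against 142 ± 66.6 (SD, n = 4). FBN1 had a value of -0.83 (SE 0.23, adjusted p = 0.0889) and passed with DESeq2 (adjusted p = 0.0139) and without the 3 libraries that stand apart (0.0414), while ELN had a value of -1.35 (adjusted p = 0.295). Posterior HOX genes were higher in 15 of 15 (median 1.80, adjusted p = 2.35e-17, adjusted p = 0.0392 with an estimated correlation), 6 rose and 11 when adjusted over the list alone. HOXD10 had 624 counts over the infrarenal and 0 over the descending libraries, at least 225-fold higher against a floor of 3 counts over the region. Pericyte markers rose as a list (median 0.64, adjusted p = 0.000669, adjusted p = 0.0392 with an estimated correlation), with NOTCH3, MCAM (1.18) and PDGFRB (0.61) called and 5 when adjusted over the list alone. Elastic fibre genes were lower in 19 of 21 (median -0.39, adjusted p = 0.000488, adjusted p = 0.0649 with an estimated correlation), with EMILIN2 called (-1.21) and 5 when adjusted over the list alone. Genes of heritable thoracic aortic disease were lower in 19 of 25 (median -0.24, adjusted p = 0.0131, adjusted p = 0.744 with an estimated correlation), with 0 called and, adjusted over the list alone, 5 lower and 1 higher. KCNA5 (2.57) and CACNA1H (2.84) rose while SULF2 (-1.59) and SFRP1 (-1.27), a WNT inhibitor, fell. The count was 132 without descending replicate 2, 152 without infrarenal replicate 2, 154 without descending replicate 3 and 161 without descending replicate 4. DPYSL5 and ACAN lost their calls in 10 and 8 of 16 such fits (adjusted p up to 0.163 and 0.130), and DESeq2 called 624. SULF2 and SFRP1 lost theirs in 6 each (0.103 and 0.111), MCAM and PDGFRB in 5 each (0.0823 and 0.0869) and P2RX1 in 2 (0.0511). The call of the heritable disease list was lost without infrarenal replicate 3 (median -0.22, adjusted p = 0.0504).

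Against the ascending aorta 556 genes differed, 228 higher and 328 lower in the infrarenal region (2017 at an unadjusted p under 0.05). HOXA10 rose by 8.55 (SE 0.65, adjusted p = 6.23e-06), HOXA9 by 8.26, NKAIN2 by 8.05, HOXA7 by 6.54 and P2RX1 by 6.18. NOTCH3 rose by 3.02 (SE 0.27, adjusted p = 3.07e-05), JAG1 by 1.73 and HES4 by 2.72. RBFOX1 (-8.89), SLC22A2 (-6.70), an organic cation transporter, CTNND2 (-6.27), RSPO2 (-5.09) and C8H8orf34 (-4.88) fell. ELN (-0.997, adjusted p = 0.518) and FBN1 (-0.28, adjusted p = 0.735) did not pass. All 15 posterior HOX genes rose, on either adjustment (median 5.51, and 5.42 with HOXB8 at its bound, adjusted p = 1.91e-41, adjusted p = 0.00227 with an estimated correlation). HOXB8 had 102 counts over the infrarenal and 0 over the ascending libraries, at least 35.5-fold higher, and HOXC9 had 576 and 1, a ratio of 601 (95% counting interval 107 to 23800). Anterior HOX genes passed as well (median 0.70, adjusted p = 0.003, adjusted p = 0.0703 with an estimated correlation), where HOXC4 (4.03), HOXD4 (3.68), HOXB5 (3.05) and HOXD3 (3.17) rose and HOXA4 fell by 2.06, with 7 and 2 when adjusted over the list alone. Across the 28 tested HOX genes the change followed the paralog number (Spearman's rho 0.754, Pearson's r 0.752, permutation p = 1e-05, the smallest that the permutations can give), a relation across genes. Genes are not independent replicates. Of the heart field and neural crest factors, HAND2 (-2.03), GATA5 (-3.07), TBX20 (-4.25), SOX9 (-3.98) and 3 more fell and TBX18 (1.26) rose (adjusted p = 0.003, adjusted p = 0.0703 with an estimated correlation, 9 and 3 when adjusted over the list alone). GATA4 had 332 counts over the ascending and 3 over the infrarenal libraries, a ratio of 106 (36 to 517). Pericyte markers were higher in 11 of 11 (median 0.96, adjusted p = 2.07e-06, adjusted p = 0.00362 with an estimated correlation), with NOTCH3, MCAM (1.43) and PDGFRB (0.98) called and 5 when adjusted over the list alone. Elastic fibre genes were lower in 17 of 21 (median -0.25, adjusted p = 0.000213, adjusted p = 0.062 with an estimated correlation), with EMILIN2 (-1.16) and MFAP2 (-1.24) called and 6 when adjusted over the list alone.

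Notch pathway genes were higher against the ascending aorta in 23 of 31 (median 0.26, adjusted p = 0.00978, adjusted p = 0.460 with an estimated correlation), with NOTCH3, JAG1 and HES4 called on either adjustment. The call of the Notch list was lost without infrarenal replicate 3 (median 0.14, adjusted p = 0.065) and without infrarenal replicate 4 (0.23, adjusted p = 0.0919). Fibrillar collagen genes were higher in 14 of 20 (median 0.06, adjusted p = 0.0142, adjusted p = 0.460 with an estimated correlation), and COL1A1 (2.09), COL1A2 (0.94) and COL6A3 (1.79) rose, 4 when adjusted over the list alone. The collagen median was -0.04 with library totals in place of TMM factors, and the list's call was lost without infrarenal replicate 4 (median 0.09, adjusted p = 0.0862). White adipocyte (2.54, adjusted p = 5.79e-05) and endothelial (0.66, adjusted p = 0.0106) markers and oxidative phosphorylation genes (0.23, adjusted p = 0.049) had positive medians and 0 called genes. Their adjusted p-values with an estimated correlation were 0.543, 0.691 and 0.691, and adjusted over the list alone 0, 1 and 0 genes passed. Without infrarenal replicate 3 the endothelial median was 0.16 (adjusted p = 0.311), and that call was lost in 4 of 16 fits. The oxidative phosphorylation call was lost in 10 (adjusted p up to 0.231), and without infrarenal replicate 1 the list passed in the other direction (median -0.15, adjusted p = 0.0378). Cardiac muscle genes (-1.69, adjusted p = 0.00797, adjusted p = 0.168 with an estimated correlation, MYH6 called and 4 when adjusted over the list alone) and Schwann cell genes (-0.79, adjusted p = 0.003, adjusted p = 0.543 with an estimated correlation, with GFAP among the genes that fell) had negative ones. Ascending replicate 1 held most of the cardiac signal, with 93 of the 128 MYH6 counts of its region, and the cardiac call was lost without it (adjusted p = 0.0614). The Schwann cell median was 0.02 without ascending replicate 4. COL1A2 and MFAP2 lost their calls in 5 of 16 fits each (adjusted p up to 0.0959 and 0.0964), MYH6 in 2 (0.0549), and SLC22A2 and GFAP without infrarenal replicate 2 (0.0516 and 0.0595). The number of genes that passed ran from 345 without infrarenal replicate 2, with 348 and 359 without ascending replicates 1 and 2, to 1001 without infrarenal replicate 1. DESeq2 called 1004 genes, the fit of these 8 libraries alone 291, and the fit without the 3 libraries that stand apart 2099, with 1134 higher and 965 lower.

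**Figure D4:**
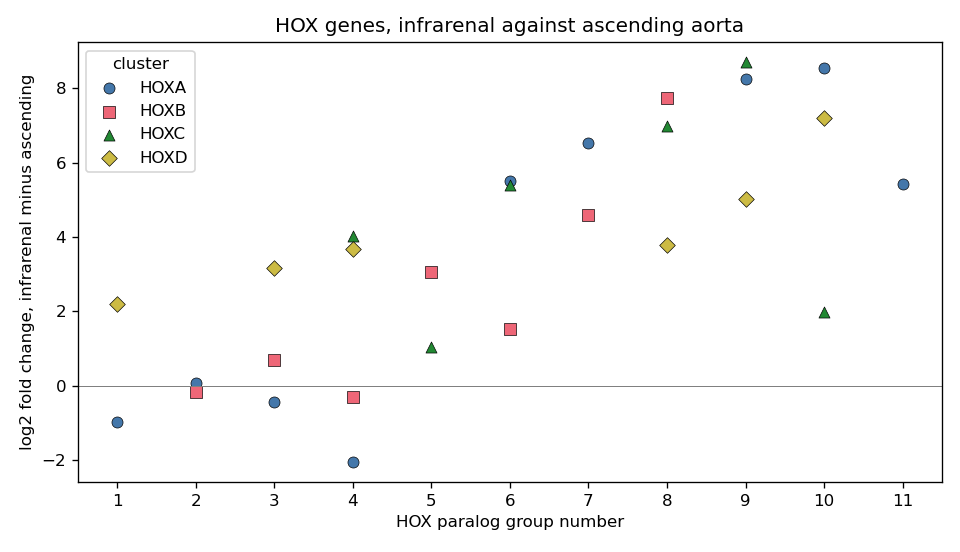
Fitted log2 fold change, infrarenal minus ascending, of the 28 tested HOX genes against their paralog group number, with 1 symbol per cluster. HOXB6 at 1.53 and HOXC10 at 1.97 are lowest among groups 6 and above, and the fitted values of HOXB8, HOXC8 and HOXC9 depend on the prior count because the ascending libraries held 0, 3 and 1 of their counts.

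The next question was which genes set the infrarenal aorta apart from each other region. In total 29 genes passed in all 3 infrarenal contrasts with the same sign, 3 higher and 26 lower, where independent lists of these sizes would share 0.000272 and 0.00608 genes. Since the 3 contrasts share the infrarenal libraries, counts were also simulated with no region effect. At an unadjusted p under 0.05, 612 genes had the same sign in all 3 contrasts, and 49 to 75 did over 20 simulated draws. Genes were drawn independently there and no library stood apart. The draws therefore do not cover an unusual infrarenal library shared by the 3 contrasts. The 3 higher genes were PCP4, HOXA10 and PTP4A1. PCP4 averaged 6.05 ± 3.72 CPM in the infrarenal region (SD, n = 4) and had at most 3 counts over the libraries of any other region, with a ratio of 130 (44.2 to 635) to the descending and 378 (67.4 to 15000) to the ascending aorta. PTP4A1 rose by 0.94 to 1.09 in the 3 contrasts, the smallest of them a call lost in 13 of 16 fits without 1 library. RBFOX1, ERC2, NPTX2, C8H8orf34 and TMEM151B were among the lower ones. With limma voom 14 genes passed in all 3, 9 higher and 5 lower. ERC2, a scaffold of presynaptic active zones, had 3 counts over the infrarenal libraries against 134, 313 and 523 over the suprarenal, descending and ascending ones, ratios of 40, 96.6 and 167 (13.4 to 197, 32.8 to 471 and 56.8 to 812). Against the descending and the ascending aorta alone, 216 genes passed with the same sign, 78 higher and 138 lower, where independent lists would share 1.45 and 3.34. With the infrarenal libraries split so that each contrast used a separate pair, 44 to 124 genes were shared over the 6 splits. The number in all 3 contrasts was 3 without infrarenal replicate 2 and 48 without suprarenal replicate 2.

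Between the neighbouring suprarenal and descending regions, edgeR called 0 genes, and DESeq2 and limma voom called 0 as well. At an unadjusted p under 0.05 there were 264, fewer than the 796 that chance alone gives. The p-values ran high here, so 0 calls do not show that the regions are alike. NOTCH3 had a value of 0.61 (SE 0.26, adjusted p = 1), with ELN at -0.64 and FBN1 at -0.26. Posterior HOX genes were higher in the suprarenal region in 14 of 15 (median 1.16, adjusted p = 7.68e-14, adjusted p = 0.165 with an estimated correlation), with 0 called and 4 when adjusted over the list alone. Endothelial markers were higher in 24 of 24 (median 0.92, adjusted p = 0.0398, adjusted p = 0.764 with an estimated correlation), and without suprarenal replicate 3 their median was -0.36. Without the 3 libraries that stand apart their median was -0.35, and camera gave an adjusted p of 0.00283. White adipocyte markers (-0.75, adjusted p = 0.00165, adjusted p = 0.639 with an estimated correlation), fibroblast markers (-0.10, adjusted p = 0.0398, adjusted p = 0.639 with an estimated correlation), oxidative phosphorylation (-0.09, adjusted p = 0.00141, adjusted p = 0.654 with an estimated correlation) and genes of heritable thoracic aortic disease (-0.16, adjusted p = 0.0107, adjusted p = 0.566 with an estimated correlation) had negative medians, and in these 5 lists 0 genes passed on either adjustment. The white adipocyte median was 0.16 without descending replicate 1, and the fibroblast median was 0.02 without suprarenal replicate 1. Without suprarenal replicate 3 the median of the heritable disease genes was -0.05 (adjusted p = 0.279), and the oxidative phosphorylation call was lost without descending replicate 1 (adjusted p = 0.0628).

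Between the descending and the ascending aorta 18 genes differed, 14 higher and 4 lower in the descending region. In all, 1074 had an unadjusted p under 0.05 where chance alone gives 796. HOXA7 (5.47), HOXC6 (4.81), HOXA9 (4.596), HOXA10 (4.23) and ADGRL3 (3.58), an adhesion G protein-coupled receptor, rose, and ART4 fell by 2.51. HOXC6 averaged 19.2 ± 9.76 CPM in the descending and 0.682 ± 0.736 in the ascending region (SD, n = 4). NOTCH3 had a value of 1.33 (SE 0.26, adjusted p = 0.0726), ELN of 0.35 and FBN1 of 0.55. Posterior HOX genes rose as a list (median 4.23, and 3.37 with HOXB8 and HOXD10 at their bounds, adjusted p = 1.46e-21, adjusted p = 0.0178 with an estimated correlation), 5 over all genes and 11 when adjusted over the list alone, and so did the anterior ones (median 0.58, adjusted p = 1.33e-08, adjusted p = 0.00661 with an estimated correlation), with HOXC5 called and 4 when adjusted over the list alone. Heart field factors were lower in 17 of 29 (median -0.15, adjusted p = 0.00739, adjusted p = 0.124 with an estimated correlation), with HAND1 called (-6.54) and, adjusted over the list alone, 9 lower and 4 higher. Their call was lost without ascending replicate 3 (median -0.02, adjusted p = 0.0598) and without infrarenal replicate 1 (-0.16, adjusted p = 0.059). White adipocyte markers were higher in 19 of 19 (median 3.21, adjusted p = 7.73e-14, adjusted p = 0.299 with an estimated correlation), with 0 called and 13 when adjusted over the list alone. Brown adipocyte markers (0.99, adjusted p = 0.0298, adjusted p = 0.299 with an estimated correlation), fibroblast markers (0.50, adjusted p = 6.86e-05, adjusted p = 0.306 with an estimated correlation), pericyte markers (0.25, adjusted p = 0.0298, adjusted p = 0.189 with an estimated correlation) and the fibrillar collagens (0.15, adjusted p = 0.0215, adjusted p = 0.326 with an estimated correlation) had positive medians, with 3, 2, 3 and 3 genes higher when adjusted over the list alone. Basement membrane genes had a median of 0.19 (adjusted p = 0.0269, adjusted p = 0.306 with an estimated correlation) with 0 on either adjustment, and cardiac muscle genes of -1.54 (adjusted p = 0.0401, adjusted p = 0.306 with an estimated correlation) with 0 called and 2 when adjusted over the list alone. Ascending replicate 1 carried the cardiac value, which was -0.43 without it (adjusted p = 0.548). The count ran from 7 without ascending replicate 3, with 10 and 8 without ascending replicates 1 and 2, to 34 without infrarenal replicate 1. DESeq2 called 177 genes, and HOXA9, HOXA10 and ART4 lost their calls in 3, 2 and 2 of 16 fits without 1 library (adjusted p up to 0.0778, 0.0759 and 0.0559). HOXC5 lost its call in 5 (0.0949) and HAND1 in 2 (0.0685). The basement membrane, brown adipocyte and pericyte lists lost theirs in 3 fits each (adjusted p up to 0.1, 0.0864 and 0.0892) and the collagen list in 2 (0.0694).

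**Figure D5:**
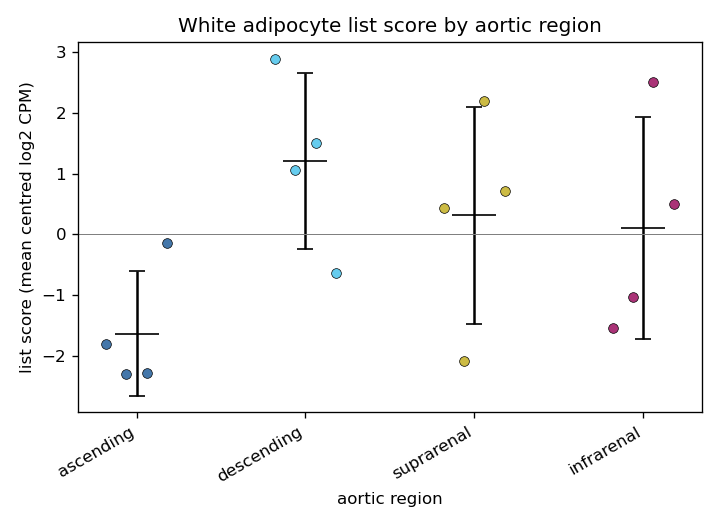
Score of the white adipocyte list (mean over 19 genes of log2 CPM, centred on each gene's mean over the 16 libraries) in each library (points), with the mean and SD of each region (bars, n = 4). The regions average -1.63 (ascending), 1.21 (descending), 0.32 (suprarenal) and 0.11 (infrarenal), and libraries of the last 3 overlap widely.

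The suprarenal aorta differed from the ascending aorta in 41 genes, 27 higher and 14 lower. In all, 876 had an unadjusted p under 0.05 where chance alone gives 796. NOTCH3 rose by 1.94 (SE 0.26, adjusted p = 0.00284), and the HOX genes HOXA7 (6.38), HOXA9 (6.25), HOXA10 (5.97) and HOXC6 (5.39) and NKAIN2 (6.04) rose. The keratin KRT8 (-2.34), ART4 (-2.20), SGIP1 (-1.59), the vesicular glutamate transporter SLC17A7 (-1.53) and the sodium pump subunit ATP1B1 (-1.48) fell. With 1 library left out, KRT8 lost its call in 11 of 16 fits (adjusted p up to 0.174), ATP1B1 in 10 (0.132), ART4 in 5 (0.0764) and NKAIN2 in 2 (0.0674). COL1A1 lost its call in 11 (0.199) and HAND1 in 3 (0.104). SLC17A7 lost it without suprarenal replicate 2 (0.0599). ELN (-0.28) and FBN1 (0.29) did not pass, with adjusted p-values of 1. Of the 17 lists that passed camera, 4 also passed with an estimated correlation. These were the posterior HOX list (median 4.68, adjusted p = 6.93e-45, adjusted p = 0.00157 with an estimated correlation, 8 called and 14 when adjusted over the list alone), the anterior HOX list (0.53, adjusted p = 1.75e-07, adjusted p = 0.00611 with an estimated correlation, 2 and 4), the pericyte list (0.68, adjusted p = 0.000106, adjusted p = 0.0114 with an estimated correlation, NOTCH3 and 3) and, lower, the heart field factors (-0.29, adjusted p = 0.000389, adjusted p = 0.0257 with an estimated correlation, HAND1 lower, and 8 lower and 3 higher when adjusted over the list alone). Of the other 13, the lists with positive medians were Notch pathway (0.39, adjusted p = 0.000849), fibrillar collagen (0.06, adjusted p = 0.00856, COL1A1 called), basement membrane (0.23, adjusted p = 0.0229), endothelial (0.71, adjusted p = 0.0145), fibroblast (0.42, adjusted p = 0.00926), white adipocyte (2.56, adjusted p = 6.17e-09), macrophage (0.45, adjusted p = 0.00377), lymphocyte (0.84, adjusted p = 0.0233) and mast cell (1.92, adjusted p = 0.00856). Cardiac (-1.19, adjusted p = 0.00386), skeletal muscle (-0.34, adjusted p = 0.016), mesothelial (-2.38, adjusted p = 0.0152, KRT8 called) and oxidative phosphorylation (-0.14, adjusted p = 0.016) genes had negative ones. The adjusted p with an estimated correlation of these 13 ran from 0.101 for skeletal muscle to 0.709 for the endothelial and oxidative phosphorylation lists. Adjusted over the list alone, 2 Notch, 4 collagen, 1 fibroblast and 3 mast cell genes were higher, 2 cardiac, 1 skeletal and 1 mesothelial gene lower, and 0 passed in the remaining 6. Without suprarenal replicate 3 the endothelial median was -0.43, and the calls of lists with medians of 0.03 (Notch and macrophage), 0.10 (fibroblast), 0.17 (lymphocyte) and 0.93 (mast cell) were lost. The collagen and oxidative phosphorylation calls were lost as well (adjusted p = 0.162 and 0.179), with medians of 0.06 and -0.15 that had hardly moved. Without ascending replicate 1 the cardiac median was -0.22 (adjusted p = 0.143), and without ascending replicate 4 the mesothelial median was 0.09. The basement membrane call was lost in 5 of 16 fits (adjusted p up to 0.112), and the skeletal muscle call without ascending replicate 2 (median -0.17, adjusted p = 0.0678). The count ran from 19 without ascending replicate 2, with 25, 20 and 21 without ascending replicate 1, ascending replicate 3 and suprarenal replicate 2, to 66 without ascending replicate 4, and DESeq2 called 184. With limma voom 42 passed, 19 higher and 23 lower.

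Tested together, the 4 regions differed in 322 genes, with 1531 at an unadjusted p under 0.05. The 5 genes with the smallest p were HOXA10 (adjusted p = 1.96e-05), HOXA9 (0.000155), PCP4 (0.00019), NOTCH3 (0.000219) and PIANP (0.00022). NOTCH3 was the only 1 of the 5 above 10 CPM in every region. PIANP averaged 21.7 ± 5.97 CPM in the ascending region and 1.71 ± 1.28, 1.18 ± 0.873 and 0.297 ± 0.153 in the descending, suprarenal and infrarenal regions (SD, n = 4). The count was 213 without infrarenal replicate 2 and 825 with DESeq2.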

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

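Values were listed where 1 library of a region lay far from the other 3. This happened in 23 of 296 groups of 4 where chance gives 15, about 1 in 20. Ascending replicate 4 held 6 of them, suprarenal replicate 3 held 5 and infrarenal replicate 1 held 3. The groups share libraries and genes, so the count does not show how many need a cause. Among list scores, suprarenal replicate 3 was high for the lymphocyte (2.081, the nearest other -0.233), Schwann cell (1.291, nearest -0.215), Notch pathway (0.6, nearest -0.018) and TGF-beta and BMP (0.259, nearest -0.105) lists. Ascending replicate 4 was high for mesothelial (3.22, nearest -0.211) and pericyte (-0.343, nearest -0.498) markers and low for ion channels of muscle (-0.331, nearest 0.006). Descending replicate 1 was high for the Notch pathway (0.163, nearest -0.094) and infrarenal replicate 1 for skeletal muscle (-0.067, nearest -0.152).

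Among CPM of named genes, the values far from the rest of their region and the nearest other were as follows. HOXA10 had 0.185 in ascending replicate 2 (0.0627) and 24.8 in infrarenal replicate 4 (40.0), HOXA9 had 0.362 in ascending replicate 4 (0.0627), HOXA7 had 92.0 in infrarenal replicate 1 (31.3), and NKAIN2 had 27.5 in suprarenal replicate 2 (5.57). CRMP1 had 3.80 (0.849) and PROM1 9.63 (1.77) in infrarenal replicate 3, SOX9 had 26.7 in suprarenal replicate 1 (5.32), PTP4A1 had 33.6 in suprarenal replicate 3 (58.0), and ACAN had 48.5 in infrarenal replicate 1 (11.8). SGIP1 had 5.62 in descending replicate 1 (7.76) and ATP1B1 had 65.8 in ascending replicate 4 (117). PCP4 had 0.0604 in ascending replicate 4 and 0.166 in descending replicate 4 (0 in the other libraries of each region).

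For the first pattern below, low depth was tested only after the result was seen, while short transcripts and a few large genes were written down before. Infrarenal replicate 1 stood apart from the other 15 libraries, with ribosomal protein genes 2.96 log2 units above genes of very long transcripts where the other libraries reached 0.65 at most. Its total of 17.63 against a median of 16.44, in units of 1e6 counts, argues against low depth. Its TMM factor was 0.779 without the 50 largest genes, where the others were at least 0.989, which argues against a few genes taking the counts. Degraded RNA or a different library preparation might give such a pattern, and a difference of the tissue itself stays open, since neither was tested.

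The 3 tests of the elastic fibre list were chosen as tests of a cause only after the result was seen, though the fits without 1 library were themselves planned. The list was lower in the infrarenal region, and without infrarenal replicate 1 its adjusted p was 9.96e-07 with a median of -0.50, which argues against that library as the cause. A smaller share of smooth muscle cells would lower contractile genes as well, and without that library the contractile median was -0.03, 0.47 above the elastic fibre median. The 2 standard errors of the difference of means, 0.24, come from the spread over genes. Genes are not independent, so this does not measure the spread between libraries. With each of the 16 libraries left out in turn the adjusted p was at most 0.0037 (median -0.45 in that fit), which argues against carried-over tissue in any 1 library as the cause. Other tissue carried over in several libraries at once is left open. Lower transcription of these genes in the infrarenal wall could be tested by in situ hybridization, and stays a hypothesis.

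Both tests of NOTCH3 were chosen as tests of a cause only after the result was seen, though the fit without infrarenal replicate 1 was itself planned. NOTCH3 was higher in the infrarenal region by 1.93, while the other pericyte markers had a median of 0.57 (SD over genes 0.46). Smooth muscle of the aortic wall expresses several of these markers, so their median cannot tell whether pericytes were more numerous. Without infrarenal replicate 1 the adjusted p of NOTCH3 was 0.000386 with a change of 1.90. A higher level of NOTCH3 in each smooth muscle cell may also explain the rise and was not tested.

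All splits of the libraries into other groups were planned before the result was seen. The splits ignored the replicate numbers, and those that mix regions widen the spread within groups, which by itself lowers their counts. Chance can be set aside no further than 1 in 60 or 1 in 35, unadjusted over the comparisons. That much holds where only the real grouping, 1 split, gave as many calls. This held for any difference (322 of its own, the highest other 1, 60 splits), the infrarenal region against the rest (474, highest other 3, 60 splits), genes in all 3 infrarenal pairs (29, highest other 0, 60 splits), infrarenal against suprarenal (32, highest other 0, 35 splits), against descending (263, highest other 0) and against ascending (556, highest other 3), and descending against ascending (18, highest other 1). For suprarenal against descending the real count was 0, which all 35 splits reach whatever they hold (highest other 1), so the splits say nothing there. Chance cannot be excluded for suprarenal against ascending, where 2 of 35 splits gave at least the real 41 and the highest other gave 43, with suprarenal replicate 1 and ascending replicate 4 exchanged.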

How the results depend on the processing

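The choices were made before the data were examined, with 2 exceptions. These were the fit without infrarenal replicate 1, ascending replicate 4 and suprarenal replicate 3, and the list tests of pairs of regions with 1 library left out. The cause was not tested where a value moved. With the replicate number as a block the counts were 84 for infrarenal against suprarenal (for NOTCH3, infrarenal versus suprarenal, adjusted p = 0.0287, a call), 432 against descending, 843 against ascending, 62 for descending against ascending, 76 for suprarenal against ascending, 532 for any difference and 80 in all 3 infrarenal pairs. Residuals correlated above 0.1 in 19 of 24 pairs of the same number (median 0.34, lowest -0.173, other numbers -0.095), so the rule for pairing was not met. Each pair at or under 0.1 held infrarenal replicate 1, ascending replicate 4 or suprarenal replicate 3. Yet 15 of 16 libraries lay closest to their own number, and 711 genes were called by number with region in the model. These values go with shared animals, which the labels do not state. Neither the main fit nor the exact permutation tests model them.

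DESeq2 gave 852 genes for the infrarenal region against the rest, 167, 624 and 1004 against suprarenal, descending and ascending, 177 for descending and 184 for suprarenal against ascending, 825 for any difference and 150 in all 3 pairs. The fit without those 3 libraries gave 1607, 241, 653, 2099, 141, 113, 1128 and 209 in the same order. For infrarenal against suprarenal and for all 3 pairs, library totals alone gave 52 and 47, no filter 51 and 45, and limma voom 15 and 14, with 9 for descending against ascending. Only the libraries compared gave 0, 291, 30 and 22 for infrarenal against suprarenal, infrarenal against ascending, descending against ascending and suprarenal against ascending. Of 8 lists called for the infrarenal region against the rest, 3 passed with an estimated correlation. With fry 4 lists passed, 3 of them among the 8.

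Leaving out 1 library in turn gave 267 to 568 genes for the infrarenal region against the rest, 3 to 52, 132 to 326 and 345 to 1001 against suprarenal, descending and ascending, 0 throughout for suprarenal against descending, 7 to 34 for descending and 19 to 66 for suprarenal against ascending, 213 to 477 for any difference, 3 to 48 in all 3 pairs, and 5 to 10 lists. NOTCH3 stayed between 1.88 and 2.05 in these fits and between 1.84 and 1.97 in the others.

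These values changed sign. ELN, suprarenal against ascending, was 0.057 without ascending replicate 2, and the fibrillar collagen median against ascending -0.037 with library totals alone. Without the 3 libraries, contractile medians were -0.096 (infrarenal against the rest) and -0.16 (against suprarenal), oxidative phosphorylation -0.102, -0.013 and -0.137 (against the rest, suprarenal and ascending), Schwann cell 0.006 and 0.057 (against suprarenal and ascending), and endothelial -0.348 (suprarenal against descending). Without infrarenal replicate 1, contractile medians were -0.028 and -0.013 and oxidative phosphorylation -0.091, -0.004 and -0.153 in the same comparisons. Without the 3 libraries, camera gave adjusted p-values of 0.028 for oxidative phosphorylation against ascending and 0.00283 for endothelial, suprarenal against descending. Without ascending replicate 4 the Schwann cell median against ascending was 0.024 and the mesothelial median, suprarenal against ascending, 0.094. Endothelial medians were -0.356 and -0.427 (suprarenal against descending and ascending) without suprarenal replicate 3 and -0.043 (infrarenal against the rest) without infrarenal replicate 3. For suprarenal against descending, white adipocyte was 0.161 without descending replicate 1 and fibroblast 0.018 without suprarenal replicate 1.

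At the other end of the fits without 1 library, these medians reached 0.39 and 0.454 for the contractile list (infrarenal against the rest and suprarenal), 0.455, 0.51 and 0.377 for oxidative phosphorylation (against the rest, suprarenal and ascending), 0.877, 1.243 and 1.692 for the endothelial list (infrarenal against the rest, suprarenal against descending and ascending), and -1.201 for the gene list Schwann cell, infrarenal versus ascending. The gene list fibroblast, suprarenal versus descending, reached -0.457 and white adipocyte -1.591. The gene list mesothelial cell, suprarenal versus ascending, reached -2.575 and ELN -0.558.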

Other observations

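Adipocyte genes differed between libraries of the same region. ADIPOQ, which encodes adiponectin, had 356, 117, 194 and 14.1 CPM in descending replicates 1 to 4, 37.1, 1.77, 345 and 63.3 in the suprarenal, 1.39, 11.2, 404 and 55.8 in the infrarenal, and 2.69, 1.23, 2.54 and 10.6 in the ascending libraries. UCP1, the uncoupling protein of brown fat, had 43.3 and 41 CPM in descending replicates 1 and 3 and 0 in all 4 ascending libraries. The 19 white adipocyte genes moved together within regions, with a median pairwise r of 0.864 between their deviations from the region means. Their score had a Spearman's rho of -0.429 with the library totals (permutation p = 0.0986) and a Pearson's r of -0.522, or -0.35 without the 2 libraries farthest from the median total.

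A small set of genes had 2 levels across the libraries. Of 21 genes with a gap of at least 2.5 log2 units, 14 were split by replicate number, where 100 permutations gave 10 at most, and 5 by region, among them PCP4, HOXA7 and HAND1. NLRP7 averaged 6.96 ± 0.884 CPM (SD, n = 4) in the libraries numbered 1 and 0 in the other 12. RPL37 averaged 585 ± 270 and 256 ± 24.3 in numbers 1 and 3 and 12.2 ± 5.75 and 5.86 ± 2 in numbers 2 and 4. CYP2E1 had 0 in number 1 and 3.15 ± 0.678, 1.74 ± 0.426 and 2.34 ± 0.733 in numbers 2, 3 and 4. With the number as the group, 666 genes were called, and 711 with region in the model.

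Along the vessel, the Spearman's rho between HOX paralog number and log2 change, across 28 genes that are not independent replicates, was 0.77 for the infrarenal region against the rest. It was 0.624 and 0.715 against suprarenal and descending, 0.789 for suprarenal against descending, 0.334 for descending and 0.607 for suprarenal against ascending.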
